A study of Mus musculus with 8 samples.

How the data were processed

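Total RNA from the livers of 8 mice was used to make biotin-labelled cRNA, which was hybridised for 18 hours to CodeLink Mouse Whole Genome Bioarrays, 1 mouse per array, per the labels' protocols. The labels name Cy5 as the label. The deposited table holds 1 intensity per probe and array on a linear scale. It has 36227 probes, the number the labels give. How the authors corrected the background and whether they normalized the intensities is not given in the sources used here. The values themselves run down to -16.7, with 1.15% below 0, so some background was subtracted. The column medians differed by up to 0.50 log2 units, so the arrays had not been brought to a common median. The labels describe quality tags for weak, irregular, saturated and contaminated spots. These tags were not used here, so neither detection nor saturation could be judged per probe. The value -9999 was read as missing: 71 probes were missing on all arrays and 64 on some.

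Mice were placed in 4 groups of 2 by their titles, which write CR where the other labels say dietary restriction. The labels say that the arrays of a group come from separate mice. All sample columns were used, and no sample was left out. Scan date and slide were not used here.

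From the deposited intensities, values below 7, the 5th percentile of the positive values, were set to 7 and log2 was taken. Because the medians differed by more than 0.1 log2 units, the arrays were quantile normalized. Quantile normalization forces all arrays to one distribution, so a shift of all transcripts in one group would not be seen. Probes with a value on all 8 arrays (36092) and a mean log2 value above the 30th percentile were tested, which left 25264. Control probes carry no mark in the table and stayed among them. A model with 1 mean per group was fitted over all 8 arrays with limma 3.58.1 in R 4.3.3, with 4 residual degrees of freedom. The 7 contrasts were DR against AL in each genotype and averaged, KO against WT in each diet and averaged, and the difference of the DR effects (KO minus WT). Tests were two-sided, with Benjamini-Hochberg adjustment over the tested probes of a contrast and a threshold of 0.05. Single values (mean correlations, shares of variance) were set against all other splits or pairings of the arrays, as exact permutation tests. Figures were drawn with matplotlib 3.10.9.

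The intensity trend alone, the robust option alone and the replicate block with crossed numbers were alternatives added after the data were seen. The choices above, the other alternatives and 36 gene lists of pathways and cell types were fixed before the data were examined. None of the lists could be tested, since the files do not pair probe numbers with genes. The rule for named genes took the largest changes past the threshold and, where few passed, the smallest p. It was written for probes with a gene symbol and for more probes per comparison. Without gene names it was applied to probe numbers and shortened to at most 2 per direction in each of the 7 contrasts. Of these, the text draws on the 3 comparisons over all 8 mice. The text names those called for DR, both lower ones for genotype, and for the difference of the DR effects the higher one with the smallest p and one of the lower ones, probe 28006, chosen for the text after its values were seen. The lists at an unadjusted p under 0.01 and 1.5-fold are an alternative threshold that had been set beforehand, while their overlap between genotypes was added after the data were seen. The exact tests against other splits, pairings and arrangements of the arrays, the p of the correlation of the DR effects included, were not among the tests fixed beforehand.

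The test was tried on simulated data with the measured level and spread of all 25264 probes, in which 200 probes were changed by DR in both genotypes. For the effect averaged over genotypes it recovered 37.0% of the 2-fold and 87.5% of the 4-fold changes, all in the right direction. It made 0 and 2 false calls. Noise was drawn independently for each probe, with its estimated spread taken as the true one. These values are therefore approximate for the measured arrays. Alternatives covered normalization between arrays, the filter on dim probes, the floor or a pseudocount, missing values, the prior variance, array weights, a replicate block, fits of the 4 arrays compared only, other thresholds and leaving out each mouse.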

Results

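Gene expression was measured in the livers of 8 male mice with one-colour CodeLink Mouse Whole Genome Bioarrays, each holding 36227 probes. The mice carried either the intact neuropeptide Y gene (Npy+/+, called WT) or a homozygous deletion of it (Npy-/-, called KO) on a mixed background of 129S-Npytm1Rpa/J and 129S6/SvEvTac. Neuropeptide Y is a peptide neurotransmitter that stimulates feeding. From 12 weeks of age each genotype was fed ad libitum (AL) or held on dietary restriction (DR), a ration equal to 70% of the mean daily intake of the AL mice. The 4 groups (WT-AL, WT-DR, KO-AL and KO-DR) held 2 mice each, and every mouse had its own array. The design asks how the liver transcriptome responds to DR, whether it depends on Npy, and whether the response to DR depends on Npy.

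The deposited table identifies probes by number, and the files do not pair these numbers with genes. Results are therefore given per probe number, and the genes and gene groups behind them, the deleted gene Npy included, were not analysed here. The genotype labels were thus not checked against the level of Npy.

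The median raw intensity ranged from 67.9 on the array of KO-DR replicate 2 to 96.1 on that of KO-AL replicate 1. Between 5.27% and 7.71% of the values of an array lay at or below the floor of 7 intensity units. After quantile normalization, 25264 probes were tested. Across these probes the 2 mice of a group correlated at r = 0.951 for WT-AL, 0.972 for WT-DR, 0.974 for KO-AL and 0.962 for KO-DR. Arrays of different groups correlated at r = 0.939 to 0.977. The mean correlation within groups, 0.965, was not distinguishable from that between groups, 0.963 (31 of the 105 ways to pair the arrays gave a mean as high, exact one-sided permutation p = 0.295). WT-AL replicate 2 had the lowest mean correlation with the other arrays, 0.952, and KO-DR replicate 2 the next lowest, 0.957. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.22 between 2 groups of 2 mice and 0.16 for an effect averaged over 4 mice against 4.

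DR was first compared with AL averaged over both genotypes. Few probes passed the threshold, and mainly large differences could pass it at this precision. By limma's moderated test with Benjamini-Hochberg adjustment, 5 probes passed an adjusted p of 0.05, of which 1 rose and 4 fell. Probe 8403 rose 4.70-fold under DR (log2 fold change 2.23, SE 0.18, adjusted p = 0.0488). Its mean log2 intensity was 8.31 ± 0.10 in WT-AL, 10.6 ± 0.12 in WT-DR, 8.00 ± 0.52 in KO-AL and 10.1 ± 0.12 in KO-DR (SD, n = 2 per group). Probe 28826, among the brightest 10% of tested probes, fell by 1.74 on the log2 scale, a 3.33-fold reduction (SE 0.11, adjusted p = 0.0256). It measured 11.4 ± 0.010 in WT-AL and 9.81 ± 0.020 in WT-DR, and 10.9 ± 0.041 in KO-AL and 8.96 ± 0.16 in KO-DR. Probe 12056 fell by 1.70, a 3.25-fold reduction (SE 0.15, adjusted p = 0.0488), from 7.21 ± 0.19 to 5.23 ± 0.067 in WT and from 7.14 ± 0.16 to 5.72 ± 0.30 in KO. The other 2 probes that fell did so 2.33-fold and 3.02-fold. In all 5, every DR mouse lay on one side of every AL mouse.

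**Figure D1:**
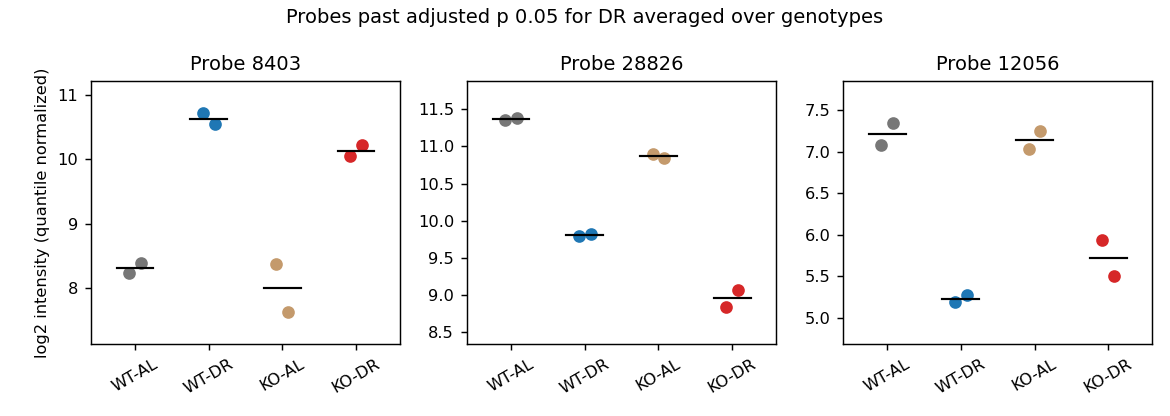
Quantile normalized log2 intensity of probes 8403, 28826 and 12056 in the 4 groups. Each point is 1 mouse, the bar is the mean of the 2 mice of a group, and the vertical axes cover different ranges. DR and AL mice do not overlap in either genotype.

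At an adjusted p of 0.10, 45 probes passed, 10 higher and 35 lower under DR, and all 45 had the same direction in WT and in KO, which their choice by the average of both genotypes largely fixes. Their absolute log2 fold changes ran from 0.88 to 3.42 with a median of 1.26. In 44 of the 45, the 4 DR mice and the 4 AL mice did not overlap. Over all tested probes, 1387 (5.49%) showed no overlap, where chance gives 2.86%; 2 of the 35 splits of the arrays into 4 and 4 separated as many (exact permutation p = 0.0571). An unadjusted p under 0.05 was reached by 2134 probes, against 1263 that 5% of the tested probes would give. In a fit with the 2 feeding groups only, 2081 probes reached it, and 4 of the 35 splits gave as many, up to 2414. The feeding group took 17.4% of the variance over all tested probes, where a split without effect takes 14.3% on average, and 6 of the 35 splits took as much (exact permutation p = 0.171, smallest possible 0.0286). The count of 5 depended on the estimate of the spread and on the filter and normalization. It was 253 (82 higher, 171 lower) with a robust prior variance that followed probe brightness, and 216 (67 higher, 149 lower) without the robust option. It was 131 with the filter on dim probes at the 50th percentile, and 0 with no filter on dim probes or no normalization between arrays. Leaving out any single mouse lowered it as well. Such a fit has fewer residual degrees of freedom, which by itself tends to lower the count. The log2 fold changes of the 5 probes then stayed at 0.916 times their value or more. A probe past the threshold can hardly fall below 0.881 times, so whether the 5 rest on single arrays is left open.

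**Figure D2:**
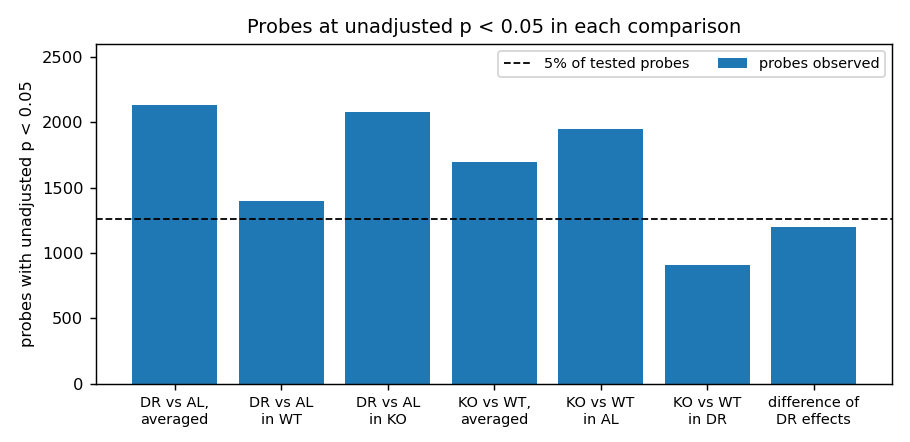
Number of tested probes with an unadjusted p under 0.05 in each of the 7 comparisons (bars), with the 1263 that 5% of the tested probes would give (dashed line). The DR effect averaged over genotypes had 2134 and the difference of the DR effects 1200.

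Taken within each genotype, with 2 mice against 2, the DR effect gave no probe past an adjusted p of 0.05 by limma. In WT the smallest adjusted p was 0.191 and 1396 probes had an unadjusted p under 0.05, which became 2747 without WT-AL replicate 1. In KO the smallest adjusted p was 0.141 and 2083 probes had an unadjusted p under 0.05, which became 1301 without KO-DR replicate 2. With a robust prior variance that followed probe brightness, 11 probes passed in WT and 45 in KO, 5 of them in both and all 5 in the same direction. Without the robust option these counts were 4 and 32. The contrast in WT rested on the mice of WT-AL: without WT-AL replicate 1, which leaves replicate 2 alone, 144 probes passed, and without replicate 2 none did. Without WT-DR replicate 1, 2 probes passed in WT. Without KO-DR replicate 2, 9 probes passed in KO. On simulated data of this design the test recovered none of the 2-fold changes and 70.5% of the 4-fold changes between 2 groups of 2 mice. A count of 0 within a genotype therefore does not exclude 2-fold responses.

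The 2 DR effects share no array and were set against each other. At an unadjusted p under 0.01 and at least a 1.5-fold change, 330 probes differed with DR in WT and 507 in KO. Of the probes chosen in WT, 266 (80.6%) had the same direction in KO, with a mean log2 difference of 0.53 in that direction against 1.04 in WT where they were chosen. Of those chosen in KO, 406 (80.1%) had the same direction in WT, with a mean of 0.42 against 1.03 in KO. Such shares were not computed over all tested probes or for other arrangements of feeding, so these have no reference here. Both lists held 110 probes, 109 of them in the same direction. These were 29 probes higher under DR in both genotypes, where independent lists would share 0.911, and 80 lower in both, where independent lists would share 2.62. Without WT-AL replicate 2 the lead of lower over higher probes was mostly lost. Both lists use the same estimate of each probe's spread, which by itself raises their overlap. Among the other arrangements of feeding within each genotype, the highest number of probes moving the same way was 18. The median change of the 29 was 1.95-fold in WT and 2.05-fold in KO, and that of the 80 was 1.95-fold in WT and 2.02-fold in KO. Leaving out a mouse lowered the 109 to between 47 (without WT-DR replicate 1) and 86 (without KO-DR replicate 1); it was 67 without WT-AL replicate 2, 58 without WT-DR replicate 2, 57 without KO-AL replicate 2 and 48 without KO-DR replicate 2. A fit without a mouse has fewer residual degrees of freedom, which by itself tends to lower this number. In the values as deposited, with all mice, the number was 63.

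Over all tested probes the 2 DR effects were weakly related across probes (Pearson r = 0.18, Spearman rho = 0.13; probes are not independent replicates). Of the 18 arrangements of feeding within genotypes, 3 gave an r as high (exact one-sided permutation p = 0.167, smallest possible 0.0556), the highest of the others being 0.25. The correlation was 0.07 with no filter on dim probes and 0.30 with the filter at the 50th percentile. It was 0.056 without KO-DR replicate 2, 0.11 without WT-AL replicate 1, and 0.12 without either WT-DR replicate 2 or KO-AL replicate 2.

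**Figure D3:**
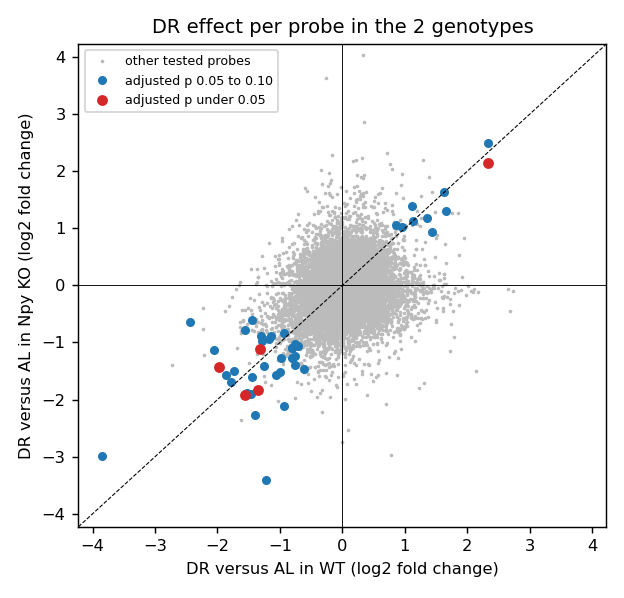
Log2 fold change of DR against AL per probe in WT (horizontal axis) and in KO (vertical axis), with equal change on the dashed line. The 5 probes past an adjusted p of 0.05 for the averaged effect are red and the other 40 of the 45 past 0.10 are blue. Both sets were chosen by the average of the 2 genotypes.

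Genotype was compared next, KO against WT averaged over feeding. No probe passed an adjusted p of 0.05 by limma, the smallest being 0.228, and 1700 probes had an unadjusted p under 0.05. Without WT-DR replicate 1, 1 probe passed and 1113 had an unadjusted p under 0.05. The 2 probes lower in KO with the smallest p are given here, though neither passed over all probes. Being chosen by p, they differ by more than their replicate error largely by construction. The intervals below are not corrected for this choice. Probe 24573 measured 9.68 ± 0.15 in WT-AL and 10.1 ± 0.10 in WT-DR, against 7.65 ± 0.41 in KO-AL and 8.37 ± 0.33 in KO-DR (SD, n = 2 per group). Its averaged log2 fold change was -1.87 (95% confidence interval -2.30 to -1.45, adjusted p = 0.228 by limma). Probe 13554 measured 8.82 ± 0.24 and 9.41 ± 0.45 in the WT groups, and 6.80 ± 0.15 and 7.12 ± 0.46 in the KO groups, a log2 fold change of -2.16 (interval -2.66 to -1.66, adjusted p = 0.228 by limma). Both passed with a robust prior variance that followed probe brightness (adjusted p = 0.00816 by limma) and without the robust option (adjusted p = 0.0161 by limma), where in each case 3 probes, all lower in KO, were called. Over all alternatives their adjusted p by limma ran from 0.00816 to 0.717, the highest without WT-DR replicate 2. Genotype took 15.4% of the variance, and 11 of the 35 splits took as much (exact permutation p = 0.314).

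Within AL mice, 1950 probes had an unadjusted p under 0.05 for genotype, and within DR mice 908 did; none passed an adjusted p of 0.05 in either diet by limma, the smallest being 0.366 and 0.388. The order of the 2 unadjusted counts turned in the values as deposited, with 1530 in AL mice and 2147 in DR mice. A count with no filter on dim probes is over 36092 probes. The count in AL mice was 1274 without KO-AL replicate 1. The count in DR mice was 1576 with no filter on dim probes, 596 without WT-DR replicate 1 and 1855 without KO-DR replicate 1. Without WT-AL replicate 1, 100 probes passed in AL mice, while none did without WT-AL replicate 2. In DR mice 3 passed without WT-DR replicate 1, and 1 without WT-DR replicate 2. At an unadjusted p under 0.01 and at least a 1.5-fold change, 475 probes differed by genotype in AL mice and 161 in DR mice. Both lists held 15 probes, 13 of them in the same direction, where independent lists would share 3.03. The estimate of each probe's spread is the same for both lists, which by itself raises their overlap. Of the probes chosen in AL mice, 270 (56.8%) had the same direction in DR mice. Their mean log2 difference in that direction was 0.058 in DR mice, against 0.93 where they were chosen. Of the 161 probes chosen in DR mice, 119 (73.9%) had the same direction in AL mice. Their mean log2 difference in that direction was 0.24 in AL mice, against 1.01 where they were chosen. These shares too were not computed over all tested probes or for other arrangements, so they have no reference here.

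**Figure D4:**
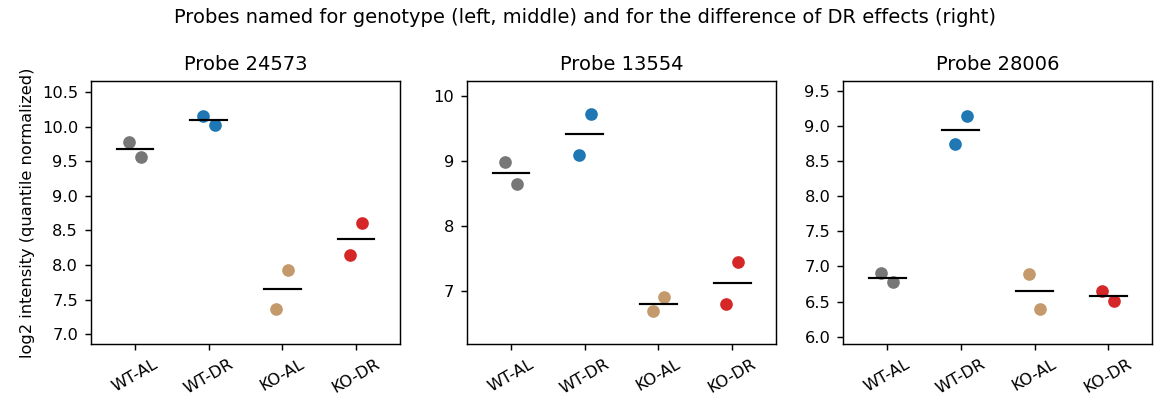
Quantile normalized log2 intensity of probes 24573 and 13554, lower in both KO groups, and of probe 28006, high only in the WT-DR mice among these 8. Each point is 1 mouse, the bar is the mean of the 2 mice of a group, and the vertical axes cover different ranges. None of the 3 passed an adjusted p of 0.05.

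Whether the response to DR differed between the genotypes was tested as the difference of the DR effects. By limma no probe passed an adjusted p of 0.05 and the smallest was 0.971. The median standard error of this difference was 0.32 log2 units. How large a difference could be found was not tried on simulated data, so absence is not shown. An unadjusted p under 0.05 was reached by 1200 probes, against 1263 that 5% of the tested probes would give. This count was 2282 without WT-AL replicate 1, 2118 in the values as deposited and 1854 with no filter on dim probes. The fit with no filter tested 36092 probes, so its 1854 is not to be set against the 1263. The difference of the DR effects took 12.0% of the variance, and 28 of the 35 splits took as much. Without WT-AL replicate 1 it took 19.7%, over 7 arrays, where each share is of a smaller total. Among single probes, probe 28006 measured 6.84 ± 0.093 in WT-AL and 8.94 ± 0.28 in WT-DR, against 6.64 ± 0.35 in KO-AL and 6.58 ± 0.092 in KO-DR (SD, n = 2 per group). Its DR effect was 2.10 on the log2 scale in WT and -0.064 in KO, a difference of -2.17 (95% confidence interval -2.92 to -1.41, adjusted p = 0.971 by limma). This interval is not corrected for the choice of the probe after its values were seen. Probe 17187 had a difference of 2.36 with the same adjusted p = 0.971 by limma, at a level among the dimmest 5% of tested probes. For the probes called for DR, the 95% confidence intervals of the difference held 0: -1.04 to 0.67 for probe 8403, -0.88 to 0.17 for probe 28826 and -0.14 to 1.26 for probe 12056. Without WT-AL replicate 1, 6 probes passed for the difference, and without any other mouse none did.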

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

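The settings with an intensity trend or the robust option alone, and the crossed block, were chosen after seeing the data. No sign reversed under any alternative, neither for the relation of the DR effects nor for the named probes where tested; the filter at the 50th percentile removes probes 12056 and 17187. The averaged DR effect called 5 probes. It called 0 as deposited, without a filter, under the replicate block and under the block with the numbers crossed in the DR groups, 11 with a pseudocount, 131 with the filter at the 50th percentile, 45 at an adjusted p of 0.10, 216 with the intensity trend alone and 253 with trend and robust prior, and kept 5 or 6 under the remaining alternatives with all mice. The stricter filter also gave 1 probe for DR in KO and 2 for averaged genotype. Trend and robust prior gave 11 for DR in WT, 45 for DR in KO, 1 for genotype in DR and 3 for averaged genotype; the trend alone gave 4, 32, 0 and 3. As deposited, 1 probe passed for averaged genotype. At an unadjusted p of 0.01 and 1.5-fold the counts were 330 for DR in WT, 507 for DR in KO, 505 averaged, 475 for genotype in AL, 161 in DR, 193 averaged and 219 for the difference. The fits of 4 arrays called 0 in each pairwise comparison. The replicate numbers were not taken to pair the mice, since the deviations of same-numbered mice from their group means correlated between -0.245 (WT-AL with WT-DR) and 0.282 (WT-DR with KO-DR) over the 6 pairs of groups. The replicate block changed no other call. The probes moved by DR in both genotypes numbered 63 as deposited. The correlation of the DR effects was 0.0698 without a filter and 0.30 with the stricter one, the DR share of variance 20.6% with the stricter filter, and the share of the difference 16.9% as deposited. Leaving out each mouse gave 0 to 144 probes for DR in WT, 0 to 9 for DR in KO, 0 to 1 averaged, 0 to 100 for genotype in AL, 0 to 3 in DR, 0 to 1 averaged, 0 to 6 for the difference and 47 to 86 moved in both genotypes. The correlation then ran from 0.056 to 0.227, the DR share from 16.8% to 24.2%, the genotype share from 14.4% to 20.5% and the share of the difference from 12.5% to 19.7%, with fewer arrays in the total. A group reduced to 1 mouse was assumed to vary like the others. As deposited, the median of all probes shifted by -0.28 for genotype in DR and -0.33 for the difference, with 2083 of 2147 and 2085 of 2118 probes lower at an unadjusted p under 0.05, against 410 of 908 and 790 of 1200 in the main values. Scaling to the 75th percentile moved the higher share at that p from 46.0% to 61.2% for DR in KO and from 34.2% to 47.3% for the difference, so no direction is read from those counts. Causes were tested only for the intensity trend; for the other settings the cause was not tested. The gene list alternatives were not run.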

Other observations

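Tests of other splits of the arrays, of the raw brightness of WT-AL replicate 2, of its deviation against KO-DR replicate 2 and of the shared WT-AL arrays were chosen after their results had been seen.

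The probes called for the averaged DR effect are the clearest signal here. In a fit with 2 groups only, the true feeding split called 2 probes and the highest of the other 34 splits called 0. Only 1 of the 35 splits thus gave as many. A count of 2, on a measure chosen after the results were seen, cannot by itself exclude chance. Other measures of the same splits do not exclude chance either. Of the 35 splits, 6 took as large a share of the variance, 4 gave as many probes at an unadjusted p under 0.05 and 2 separated as many probes. With a robust prior variance that followed brightness the same fit called 194 probes, against at most 1 in any other split. Raw brightness differed little between the diets, as the log2 medians of the DR arrays (6.09 to 6.53) and of the AL arrays (6.26 to 6.59) overlapped. The called probes did not overlap, but their choice by this comparison largely fixes that. It therefore does not test brightness as a cause. With means differing by only -0.041, brightness as a covariate could hardly move the 45 probes past 0.10, which kept a median of 1.003 times their change. Leaving out any mouse kept the 5 called probes at 0.916 times their change or more, but a probe past the threshold can hardly fall below 0.881 times, so this leaves one atypical array open. Without any one mouse fewer probes passed, but such a fit also has less power. A response of these transcripts to DR that is shared by both genotypes stays as a hypothesis, found and tested on the same data.

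The number of called probes rose from 5 to 216 with an intensity trend in the prior variance. The median residual SD was 0.36 log2 units in the dimmest of 4 equal brightness bins of probes and 0.15 in the brightest. A spread that falls with brightness is thus a candidate explanation. Of the added calls, 91.9% lay above the median brightness. With such a spread the trend itself lowers the prior variance of bright probes, so this share is no separate support. A few probes of extreme spread are argued against, as the robust option alone called 5. The trend called 5, 21, 60 and 167 probes from the dimmest to the brightest bin when combined with the robust option.

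WT-AL replicate 2 lay apart from the other arrays, with a root mean square deviation of 0.44 log2 units from the median array against 0.40 for KO-DR replicate 2, the next. Low raw brightness alone is argued against, because 3 arrays had a lower median. KO-DR replicate 1 (78.7) and KO-AL replicate 2 (76.7) lay just below the 78.9 of WT-AL replicate 2. They deviated by only 0.30 and 0.32 log2 units. KO-DR replicate 2, the lowest at 67.9, deviated next most, so a part played by brightness is not excluded. Noise of dim probes stays open. In the brightest bin the deviation of WT-AL replicate 2 was 0.965 times that of KO-AL replicate 1, the highest there among the others. Against KO-DR replicate 2 it was 1.07 times as large in the brightest bin and 1.01 times in the dimmest. In the dimmest bin KO-DR replicate 2 itself deviated by 0.59 log2 units, near the 0.60 of WT-AL replicate 2. The remaining arrays deviated by 0.38 to 0.48 there. The comparison with KO-DR replicate 2 therefore cannot tell whether the excess of WT-AL replicate 2 lay in dim probes. A difference between individual mice was not tested. When this array alone stood for WT-AL, 144 probes passed for DR in WT.

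The genotype split and the split for the difference of the DR effects called 0 probes in the 2-group fit, so all 35 of 35 splits gave as many by construction and this count tests neither. The highest of the other splits, 2, is the feeding split. At an unadjusted p under 0.05, 9 of the 35 splits gave as many probes as genotype and 22 as many as the difference, so chance cannot be excluded for either.

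For the 109 probes moved by DR in both genotypes, 1 of the 18 arrangements of feeding within genotypes gave as many, the highest other being 18. With 18 arrangements a share under 0.05 cannot be reached.

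One hypothesis was that lack of Npy in AL mice resembles DR in WT mice. The genotype effect in AL and the DR effect in WT correlated at r = 0.49 across probes, but both are taken against the same 2 WT-AL mice. Unchanged groups simulated with the measured spread gave r = 0.65. The covariance was 0.0618 against 0.0833 simulated, a difference of -0.0215, so a shared effect beyond the common arrays was not seen. The simulation took probes as independent and scaled the spread of WT-AL by its 2 mice only. Such an effect is therefore not excluded.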
